A study of Homo sapiens with 5 samples.

How the data were processed

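Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in MIA PaCa-2, an established human pancreatic cancer cell line. Per the labels, MED17, MED30 and MYC were mapped in cells under normal culture, and MYC was mapped again in a MIA PaCa-2 line carrying a doxycycline-inducible short hairpin RNA against MED30 (shMED30), without doxycycline and after 3 days of it. Each of these 5 groups holds 1 library, so no comparison has a replicate check and no p-value is given across peaks or genes. Per the labels' protocols, chromatin for the Mediator subunits was fixed with 2 mM disuccinimidyl glutarate for 20 min and then 1% formaldehyde for 10 min, chromatin for MYC with 1% formaldehyde for 10 min alone, and reads were paired, 100 bp long. Fixation therefore differs wherever a Mediator list is set beside a MYC list.

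The submitters' processing notes name Trim Galore, Bowtie2, deepTools, MACS2 and the hg38 build; their versions, and whether an input control was used in peak calling, are not given in the sources used here. Each deposited file is a peak list in the narrowPeak layout for a single library. The deposited fold enrichment is a ratio of the fragment pileup at the peak summit to the local background. Significance is deposited as −log10 p and −log10 q of each peak, and the deposited score is 10 times −log10 q, rounded down. These values are the authors' own and were used only to describe, rank or filter peaks within a list. The smallest −log10 q shows that 3 lists (MED17, MED30 and parental MYC) start at a q of 0.05 and the 2 lists from the shMED30 line at 0.1.

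Gene positions came from the RefSeq table for GRCh38.p14, which gives the start and end of each gene without its strand. The planned distance to a transcription start site was replaced by the distance to either end of a protein-coding gene. A peak within 1 kb of one is called a gene boundary peak, and promoters inside a gene are missed. Because strand was not known, a gene boundary peak can lie past the gene it is counted for, near a neighbouring gene. The table held 20037 protein-coding genes. With all boundaries moved by 100 kb, the gene boundary share fell to 7.08% or less in each list, from 64.9% in the MED17 list and 17.1% in the doxycycline list. Peaks in 29 stretches of over 2 Mb without any annotated gene, most of them around centromeres, and peaks on contigs outside the main chromosomes were treated as a class of their own; all other peaks are referred to as peaks on chromosome arms. No genome sequence was used here, so the planned share of peaks with the MYC recognition sequence CACGTG was not computed.

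Read totals are not part of the peak lists. Relative depth was recovered from the lists themselves: fold and p together fix the summit pileup and the local background of a peak, if fold is (pileup + 1)/(background + 1) and p is a Poisson tail. Both values were matched within 0.002 log10 units for 99.5% to 99.9% of peaks per list. The lowest local background in a list was taken as the genome-wide background pileup, which scales with the number of fragments and their length.

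Overlap means at least 1 shared bp. Shares of peaks carry exact (Clopper-Pearson) 95% intervals, which cover counting error only and treat peaks as independent. Each overlap was set beside 100 random placements of the first list on the main chromosomes, once uniformly within each chromosome and once keeping each peak in its class (gene boundary, gene-free stretch or elsewhere). Placements were not matched on expression and were not limited to sequence where reads can map. Retention with doxycycline was compared between MYC peaks with and without a MED30 peak by a Mantel-Haenszel odds ratio over 10 bins of fold enrichment by gene boundary status. Gene lists (20, with olfactory receptor genes as a list of silent genes) were compared with 10000 random lists of protein-coding genes of the same size; for retention, random lists were drawn from genes with a peak in the no-doxycycline list, matched on fold enrichment. A gene counted as keeping its peak if any of its boundary peaks without doxycycline overlapped a peak with it, so genes with several peaks had more chances. The random lists describe these libraries and are not a test over replicates. Those for counts of bound genes were drawn from all protein-coding genes and were not matched on expression.

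The genes named are MYC, MED30, MED17, NCL, NPM1, ODC1, CDK4, LDHA, CAD and CCND2; the genes at the 10 strongest gene boundary peaks shared by MED17, MED30 and parental MYC, kept with doxycycline or lost with it; those at the 5 strongest of MYC without Mediator, both Mediator subunits without MYC, and gained with doxycycline; and up to 4 members of each gene list per class with the highest fold. Since the rule left open which list's fold decides, parental cells were described by MYC fold, or by MED30 fold where MYC had no peak, a choice made later. Some genes that the rule takes, and 1 gene list, are not reported here, for reasons that do not depend on their values. Apart from that, this rule, the gene lists, the comparisons and the alternative settings were fixed before the data were examined, except those alternatives named as later additions with the results they change.

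A depth model was added once the difference in background pileup had been seen. Summit pileups of parental MYC peaks were scaled down to the background of each shMED30-line library, 1 scale for enrichment was fitted to the number called without doxycycline, and the number expected with doxycycline was predicted by lowering depth alone, with 200 bootstrap draws of peaks. On simulated data, the overlap counts differed from those of bedtools by 0 in 2000 intervals, the true pileup was recovered for 100% of 3000 peaks, 1.03% of 3000 peaks with shuffled p were wrongly accepted, and over 50 draws enrichment ratios of 1 and 0.7 were estimated as 0.999 ± 0.043 and 0.693 ± 0.035 (mean ± SD) from 4000 peaks, and an odds ratio of 2 as 2.00 ± 0.058 from 20000 peaks. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1.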

Results

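Peak lists were available for 5 ChIP-seq libraries from MIA PaCa-2 cells, 1 per group: MED17 and MED30, subunits of the Mediator complex that links transcription factors to RNA polymerase II; MYC in the parental cells; and MYC in the shMED30 line without and with 3 days of doxycycline. The lists held 13172 peaks for MED17, 12040 for MED30, 14331 for parental MYC, 7158 for MYC without doxycycline and 4621 with it. The background pileup recovered from the lists was 1.60 fragments for MED17, 1.65 for MED30 and 2.56 for parental MYC, but 0.310 for the shMED30 line without doxycycline and 0.186 with it. The parental MYC library was thus 8.27 times as deep by this measure as the no-doxycycline library, and the doxycycline library 0.599 times as deep. The median summit pileup was 21 to 22 fragments in the 3 lists from parental cells, 8 without doxycycline and 6 with it. Errors given below are counting intervals within these libraries, as no group had a replicate.

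Gene boundaries were the most frequent location of peaks in parental cells. Gene boundary peaks made up 64.9% of the MED17 list (95% interval 64.1 to 65.7%), 59.4% of the MED30 list (58.5 to 60.2%) and 48.0% of the parental MYC list (47.2 to 48.8%). In the shMED30 line the share was 20.4% (19.5 to 21.3%) without doxycycline and 17.1% (16.0 to 18.2%) with it. Gene-free stretches and contigs held 10.3% of the peaks of each Mediator subunit, 27.0% of parental MYC peaks, 63.6% of MYC peaks without doxycycline and 57.5% with it. Among peaks on chromosome arms, the gene boundary share was 72.4% for MED17, 66.1% for MED30, 65.8% for parental MYC, 56.0% without doxycycline and 40.1% with it. In all, 9594 of 20037 protein-coding genes had a MED17 peak at a boundary, 8346 a MED30 peak and 7813 a parental MYC peak, against 1713 and 943 genes with a MYC peak in the shMED30 line without and with doxycycline.

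**Figure D1:**
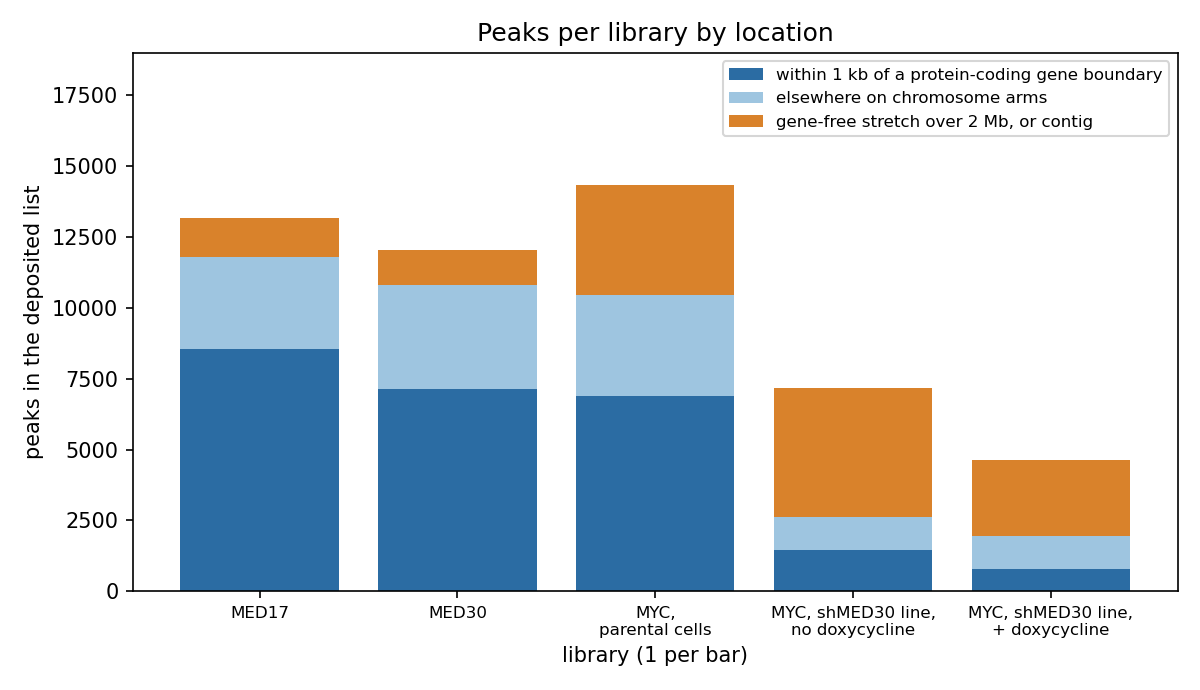
Number of peaks in each deposited list (y axis) for the 5 libraries (x axis, 1 library per bar), split by location. Gene-free stretches and contigs hold 10.3% of each Mediator list and 63.6% and 57.5% of the MYC lists from the shMED30 line.

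The first comparison asked where MED17 and MED30 were bound together. MED30 peaks overlapped MED17 peaks most often at gene boundaries, where 89.9% (89.2 to 90.6%) did, against 9308 of 12040 in the whole list (77.3%, 76.6 to 78.1%). That share depended on the definition of overlap and was 49.6% for peak centres within 250 bp and 50.7% for a reciprocal overlap of at least 50%. In the other direction 71.5% (70.7 to 72.2%) of MED17 peaks overlapped MED30. Both subunits had peaks at NCL and NPM1, which encode the nucleolar proteins nucleolin and nucleophosmin (MED30 folds 9.58 and 8.50), at ODC1, the rate-limiting enzyme of polyamine synthesis (6.98), at LDHA, lactate dehydrogenase A (9.77), and at MED17 itself (7.82). CDK4, a cyclin D-dependent kinase of the cell cycle, had a MED17 peak (4.17) and no MED30 peak, and CCND2 had neither. With MED30 peaks placed at random on the main chromosomes, the mean overlap with MED17 was 0.835% for uniform placement and 11.3% within class (highest of 100, 11.8%), against 77.6% observed there.

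Sites of 1 subunit alone lay less often at the boundaries of protein-coding genes than shared sites. Gene boundaries held 26.4% of the 2732 MED30 peaks without MED17, against 69.0% of those with it, and 53.1% of the 3757 MED17 peaks without MED30, against 69.6%. Their median fold was lower too, 4.07 against 5.07 in the MED30 list and 4.44 against 5.20 in the MED17 list. Of the 31 genes for Mediator subunits and the kinase module, 30 had a MED17 peak and 24 a MED30 peak, where random lists averaged 14.9 and 12.9 and none of 10000 reached either count. With the upper 50% of each list by fold, 20 had a MED17 peak (no random list reached this) and 12 a MED30 peak (506 did). MED30 itself was the gene without a MED17 peak. Without replicate libraries, a site in 1 list only can be a site just under the calling threshold in the other.

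The second comparison asked where MYC and Mediator were bound together in parental cells. Genes of ribosome production and translation had peaks of MYC and of both subunits. These are counts per gene: each protein had a peak within 1 kb of either gene boundary, and the peaks need not overlap. At EIF4G1, for example, the strongest MED17 peak lay past the upper end of the gene, and those of MED30 and MYC at its lower end. All 20 ribosomal protein genes examined had a peak of MED17, MED30 and MYC, including RPL5 (MYC fold 14.8), RPL8 (12.1), RPS19 (11.5) and RPS2 (10.1), and so did all 15 translation factor genes, including EEF1B2 (12.0), EIF5A (11.3), EIF3B (11.0) and EIF4G1 (10.3). Random lists of these sizes averaged 6.21 and 4.67 such genes, and none of 10000 reached the observed count. The random lists were not matched on expression, so these and the later counts do not separate targeting of a gene list from binding at active genes in general. Of 20 ribosome biogenesis genes, 17 carried all 3, including NPM1 (11.3), NCL (10.2), NOLC1 (9.47) and POLR1B (9.40).

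Over the whole lists, 8225 of 14331 parental MYC peaks overlapped MED30 (57.4%, 56.6 to 58.2%) and 8880 overlapped MED17 (62.0%, 61.2 to 62.8%). At gene boundaries the shares were 77.8% (76.8 to 78.7%) and 86.5% (85.7 to 87.3%), and in gene-free stretches and contigs 26.4% and 28.4%. Random placement within class, again not matched on expression, gave means of 7.29% for MED30 and 8.92% for MED17, against 57.8% and 62.3% observed on the main chromosomes. The overlap with MED30 was 40.4% in the lowest of 10 equal bins of MYC peaks by fold and 74.5% in the highest. Merged into regions on chromosome arms, the 3 lists gave 15583 regions, of which 6476 (41.6%) held all 3 proteins and 1829 (11.7%) held MYC alone. Gene boundaries took 78.8% of the former and 28.6% of the latter.

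Metabolic and transcription genes were bound by all 3 proteins as well. This held for 17 of 20 nucleotide synthesis genes, with NME1 (MYC fold 12.3), ATIC (10.7), CTPS1 (9.87) and MTHFD2 (8.47) the highest, and CAD, which starts pyrimidine synthesis, at 8.04. It held for 12 of 16 glycolysis genes, led by the glucose transporter SLC2A1 (8.11) and LDHA (7.73), for 15 of 18 RNA polymerase II and elongation genes, led by the kinases CDK13 (6.78) and CDK12 (5.75), and for 13 of 21 cell cycle and replication genes, led by the helicase subunit MCM7 (13.2). At most 35 of 10000 random lists reached any of these counts, but with the upper 50% of each list by fold, 3 glycolysis and 2 cell cycle genes carried all 3, which 1406 and 5387 lists reached. Of 14 genes of the MYC network, 8 carried all 3 (367 lists reached this), including MXD1 (10.5), a MAX partner that competes with MYC, and MAX (7.81), the obligate partner of MYC. Of 10 genes that MYC is known to repress, 5 carried all 3, including TXNIP (6.39); 1684 lists reached this count.

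Some stress and mesenchymal genes had Mediator peaks without MYC. The integrated stress response list had 8 of 13 genes with MED17 (2340 lists reached this), 10 with MED30 (102, but 1840 for the 5 left with the upper 50% of peaks by fold) and 6 with MYC (3920), with DDIT4 (MED30 fold 6.86) bound by both subunits and not by MYC. Mesenchymal genes had 7, 8 and 4 of 15 with MED17, MED30 and MYC, counts reached by 6350, 2497 and 9010 lists, among them ZEB1 (MED30 fold 5.99), CD44 (5.62) and AXL (4.90) with Mediator alone. The difference between MYC and Mediator in these lists was not tested, and fixation differed between them.

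Genes of other cell types and of the classical and basal pancreatic cancer lists had few peaks, and at most 974 of 10000 random lists were as low. No acinar gene of 15 had a peak of any of the 3 proteins, and 0, 4 and 6 of 10000 random lists were as low for MED17, MED30 and MYC. Olfactory receptor genes had 1 MED17 peak, 1 MED30 peak and 0 MYC peaks in 390 genes, where random lists averaged 187, 163 and 152. The islet list had SYP alone of 15 genes, with all 3 proteins (6, 34 and 64 lists as low). The immune list had CD8A with all 3 and CD4 with both subunits (of 14 genes; 106, 325 and 105 lists as low), and the fibroblast list ACTA2 with all 3 and COL1A2 with both subunits (of 11), where 452, 974 and 386 lists were as low. Of 16 classical pancreatic cancer genes, ERBB3 and FOXA3 were counted with all 3 and CDX2 with MYC alone. Of 14 basal ones, ITGB4 carried both subunits and S100A2 MED30 alone. As low as the classical list were 29, 114 and 797 lists, and as low as the basal one 13, 325 and 10. The peaks counted for ERBB3 and CD4 began past the upper end of the gene, and those for FOXA3 ended below its lower end. Such peaks may belong to a neighbouring gene. The same limit holds for lists with high counts: the strongest MED17 and MED30 peaks counted for MCM4, a cell cycle gene, ended below its lower end.

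**Figure D2:**
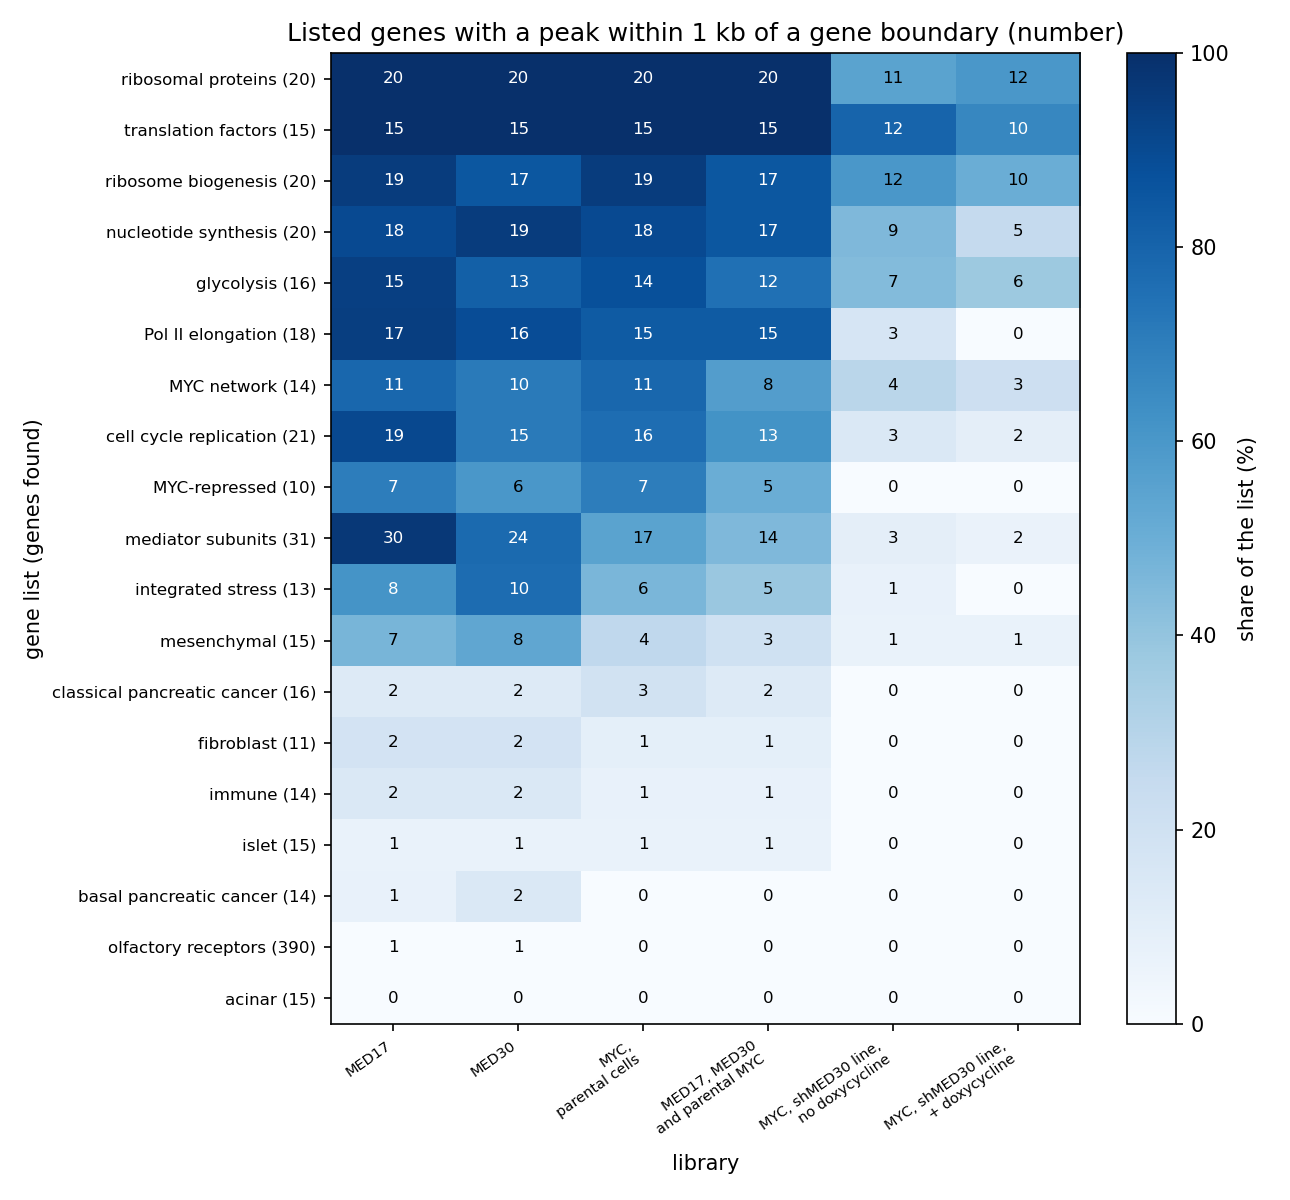
Number of genes of each list (rows, genes found in parentheses) with a peak within 1 kb of a gene boundary in each library (columns); the column for MED17, MED30 and parental MYC counts genes with all 3, and the colour gives the share of the list in percent. All 20 ribosomal protein genes and no acinar gene have a peak of all 3 proteins.

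The strongest gene boundary peaks shared by all 3 proteins, by mean rank, were at SRSF6 (chromosome 20, 43457745 to 43458588, MYC fold 13.2), RPS19, RPS23, HSP90AB1, CYCS with SPMIP4, CCT2, PPIA, PON2, HERPUD1 and POLR3D. SRSF6 encodes a splicing factor, HSP90AB1 and CCT2 encode chaperones, and POLR3D a subunit of RNA polymerase III. The strongest MYC peaks without either subunit were at MLLT1 (11.2), TBL1X (10.9), PFN2 (10.9), SHANK3 (8.47) and SRC (8.25). The strongest MED30 peaks shared with MED17 and lacking MYC were at IGBP1C (18.6), TAF12 (15.2), TMEM107 (13.7) and SDC4 (12.8).

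At the MYC gene (chromosome 8, 127735434 to 127742951) both Mediator subunits had a peak, at 127736174 to 127737206 for MED17 (fold 3.33) and 127735092 to 127736400 for MED30 (3.99). None of the 3 MYC lists had a peak there. The nearest strong MYC site, singled out after its values were seen, lay 51.3 kb past the end of MYC in the parental list, at the lower boundary of PVT1, a long noncoding RNA gene (127794524 to 128101256). The peak spanned 127794229 to 127794826 with a fold of 8.13 (percentile 92.9 of its list), and peaks at the same boundary had folds of 12.1 (97.7) without and 10.4 (97.3) with doxycycline in the shMED30 line. MED17 had a weak peak at this boundary (3.31, percentile 5.16), and MED30 had none.

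**Figure D3:**
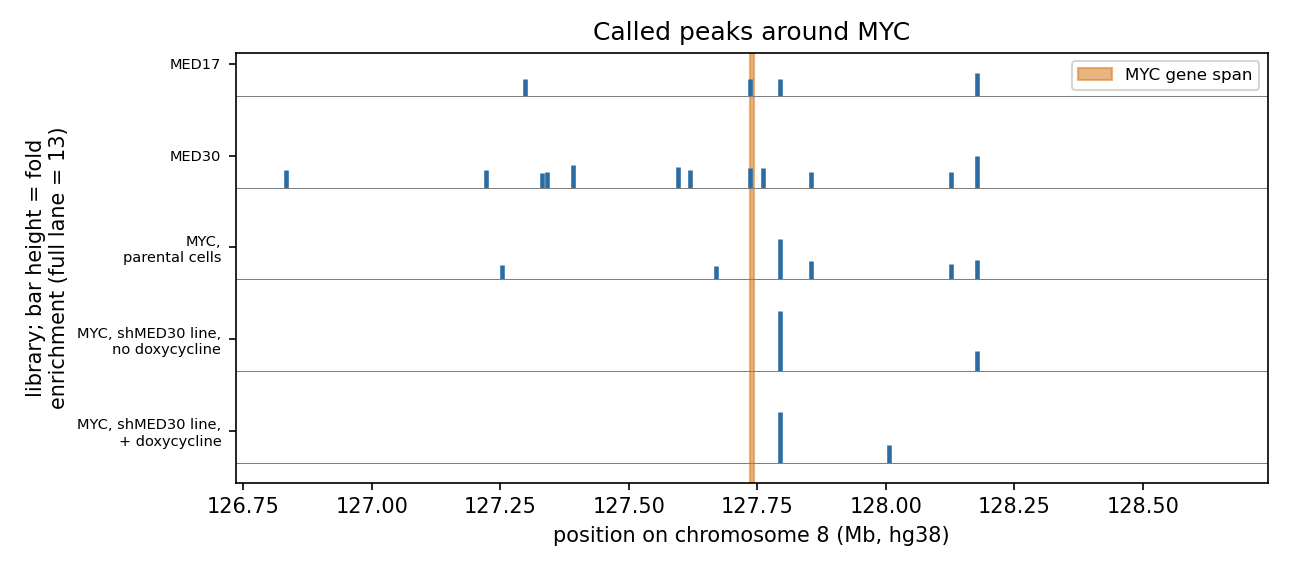
Called peaks within 1 Mb of the MYC gene on chromosome 8 (x axis, position in Mb, hg38) in the 5 libraries (lanes); the height of each bar is the authors' fold enrichment. Both Mediator subunits have a peak at MYC (folds 3.33 and 3.99), and the tallest bar in each MYC lane is the peak at the PVT1 boundary (8.13, 12.1 and 10.4).

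The third comparison asked how MYC binding differed after induction of the hairpin against MED30. The MED30 transcript and protein were not analysed here, so the knockdown could not be checked; at the MED30 gene itself (chromosome 8, 117520713 to 117540262) the doxycycline list had a MYC peak of fold 10.3 at 117520865 to 117521060, and the other 4 lists had none. Of the 20 ribosomal protein genes examined, all 11 with a MYC peak without doxycycline kept it, while RPS25 and RPL23A, which are outside that list, lost theirs. Those kept included RPL5 (fold 10.5 without doxycycline), RPS19 (10.3) and RPS3 (9.27). Random lists matched on the no-doxycycline peak kept 6.12 on average, and 4 of 10000 kept all 11; with a matching on the parental MYC peak, added after this result was seen, they kept 7.50, and 138 kept all 11. Over all genes with a boundary peak without doxycycline, 573 of 1713 (33.5%) kept it.

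Across the list, 5140 of 7158 peaks (71.8%, 70.7 to 72.8%) had no overlapping peak with doxycycline. The lost share was 67.2% (64.8 to 69.6%) at gene boundaries, 74.3% (71.6 to 76.8%) elsewhere on chromosome arms and 72.7% (71.3 to 73.9%) in gene-free stretches and contigs. It followed peak strength: 11.0% were kept in the lowest of 10 bins by fold and 77.4% in the highest, and the median summit pileup was 7 for lost and 11 for kept peaks. The doxycycline library had 0.599 times the background pileup of the other (0.186 against 0.310 fragments). The MYC lists without knockdown differed as well: 52.0% (50.8 to 53.1%) of no-doxycycline peaks had no parental peak, and 75.5% of parental peaks had none in the no-doxycycline list. On chromosome arms, 36.8% (34.6 to 38.9%) of no-doxycycline peaks with a parental peak were kept, against 8.56% (6.53 to 11.0%) of those without.

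Of 12 ribosome biogenesis genes with a peak, 10 kept at least 1, including NCL (12.8), BOP1 (11.0), POLR1B (9.81) and NOLC1 (9.46). Peaks were lost at GAR1 (8.47) and NOP16 (5.90), and 485 of 10000 matched lists kept as many genes. Translation factor genes kept 9 of 12 (741 lists), including EEF1B2 (13.0), EIF3A (11.8), EIF5A (10.6) and EIF4A1 (10.1). The lost peaks were at EIF4H (7.28), EIF1AX (5.69) and EIF2S2 (4.91), and EIF4H had another peak with doxycycline that did not overlap. Glycolysis genes kept 5 of 7 (1831 lists), including LDHA (12.1), ENO1 (7.97), PGK1 (7.68) and HK2 (7.09), and lost those at SLC2A1 (8.39) and GAPDH (3.82). ODC1 kept its peak (10.7).

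Of 9 nucleotide synthesis genes with a peak, 5 kept at least 1 against 4.95 in matched lists, 6545 of which kept as many. Those kept were at MTHFD2 (12.7), CTPS1 (10.4), ATIC (8.77), PPAT (8.34) and GART (6.22), and those lost at NME1 (11.5), CAD (9.76), DHODH (4.44) and SHMT2 (3.33). RNA polymerase II and elongation genes lost all 3, at CDK13 (5.15), CDK9 (4.20) and CCNT2 (4.10), where matched lists kept 0.357 on average. MYC network genes kept 3 of 4, at MXD3 (10.1), MXD1 (8.71) and MLXIP (6.78) but not MLXIPL (5.68). Cell cycle genes kept MCM7 (9.01) and lost MCM4 (6.17) and PLK1 (5.87), and Mediator genes kept MED20 (10.6) and lost MED22 (4.14) and MED17 (3.35). ATF4 (7.98), the single stress gene with a peak, lost it. The MYC-repressed, classical, basal, acinar, islet, immune, fibroblast and olfactory lists had 0 genes with a peak in either list from the shMED30 line. Outside the olfactory list this is an ordinary count, as 2391 to 6243 of 10000 random lists also had 0. For the 390 olfactory genes, random lists averaged 33.3 genes without and 18.3 with doxycycline.

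The strongest gene boundary peaks kept were at MGME1 with SNX5 (chromosome 20, 17968444 to 17968840, fold 17.5), AIMP2 with PMS2 (17.3), CCDC88C (16.9), RABGGTB, GDI2, HMGN1, RPS23, RPSA, WDR43 and ASPRV1 with PCBP1. The strongest lost were at URB1 (chromosome 21, 32392801 to 32393169, fold 13.8), NME1 with NME1-NME2 (11.5), RPS25 with TRAPPC4 (11.4), RGS10, IMPA2, ZNF121, RPL23A, CDK10, C6orf62 and ANXA2. URB1 takes part in ribosome biogenesis, and RPS25 and RPL23A are ribosomal protein genes outside the list examined. All 10 lost sites had a parental MYC peak and peaks of both Mediator subunits.

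With doxycycline, 2539 peaks had no counterpart without it, and 310 of them were at gene boundaries. Of those 310, 258 (83.2%, 78.6 to 87.2%) overlapped a parental MYC peak, and their median summit pileup was 5. The 5 strongest were at MED30 (10.3), SCARB1 (8.02), SNRPE (7.89), HTATIP2 (7.84) and FJX1 (7.73), and all but MED30 overlapped a parental MYC peak.

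The fourth comparison asked whether sites with MED30 in parental cells kept MYC more or less often. On chromosome arms, 572 of 1509 no-doxycycline peaks with a MED30 peak were kept (37.9%, 35.5 to 40.4%), against 201 of 1096 without (18.3%, 16.1 to 20.8%). Of the 10 strongest kept sites, 9 had a MED30 peak, with CCDC88C the exception, and all 10 of the strongest lost sites had one. Across all peaks, the odds of being kept were 1.83 times as high with a MED30 peak (1.58 to 2.11), after stratifying by fold and gene boundary status. With MED17 in place of MED30 the ratio was 1.88 (1.62 to 2.17). Among no-doxycycline peaks with a parental MYC peak it was 1.44 (1.22 to 1.70).

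**Figure D4:**
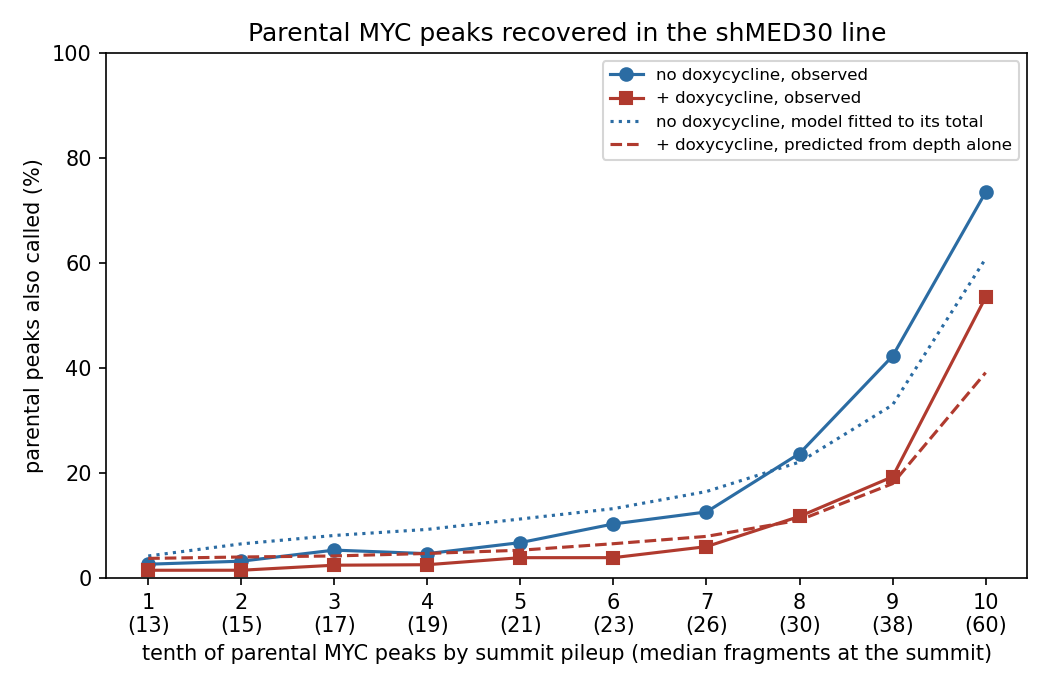
Share of parental MYC peaks on chromosome arms that were also called in the shMED30 line (y axis, percent), in 10 equal bins of their summit pileup in the parental list (x axis, median fragments in parentheses); points are observed shares, and dotted and dashed lines are the depth model without and with doxycycline. In the top bin, 73.5% were called without and 53.5% with doxycycline, against 60.9% and 39.2% in the model.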

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

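Of 55 shares and counts recomputed under another setting, 15 stayed within the interval of the reported share or within 1.5 times the reported count, and 40 moved beyond it; settings on q, on gene-free stretches and contigs, on recovered pileup and, for the odds ratio, on parental peaks were chosen after seeing the data. The odds ratio of retention by MED30 stayed above 1, with its interval, in all 10 settings, from 1.44 to 2.86, and 8 of these lay within the reported interval of 1.58 to 2.11; 2.86 came without strata and 1.44 from peaks that also had a parental MYC peak. Overlap shares depended on how overlap was defined and on peak strength and location. The shallow libraries of the shMED30 line limit calls to summits of at least 4 fragments without and 3 with doxycycline. No paired analysis was possible because each group holds 1 library and the labels give no replicate numbers. The planned settings of the CACGTG share were not run, as no genome sequence was used here. The causes of the shifts below were not tested, apart from those that follow from how a setting selects peaks.

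The shares of MED30 peaks overlapping MED17, of parental MYC peaks overlapping MED30 and of MYC peaks lost with doxycycline became 50.7%, 38.3% and 83.9% with a reciprocal overlap of at least 50%; 49.6%, 44.0% and 81.1% with peak centres within 250 bp; 59.9%, 42.4% and 65.5% for the upper 50% of each list by fold; 73.3%, 60.3% and 63.5% for equal numbers of strongest peaks; 89.9%, 77.8% and 67.2% at gene boundaries; 58.9%, 38.6% and 73.0% away from them; and 79.2%, 68.9% and 70.3% without gene-free stretches and contigs. The lost share was 59.8% among peaks that also had a parental MYC peak. The gene boundary shares of MED17, MED30, parental MYC, no-doxycycline and doxycycline peaks became 68.1%, 62.5%, 51.0%, 21.9% and 19.1% within 2.5 kb, 61.9%, 56.8%, 44.7%, 18.1% and 15.2% within 0.5 kb, and 72.4%, 66.1%, 65.8%, 56.0% and 40.1% without gene-free stretches and contigs. The doxycycline share was 20.1% at a q of at most 0.05. Of the 19 gene lists other than olfactory receptors, those in the top 2.5% of random lists fell from 9 to 4 for MED17 and from 11 to 5 for MED30 with the upper 50% of peaks by fold. Ribosome biogenesis, nucleotide synthesis, cell cycle and MYC network genes left the top for both subunits, glycolysis genes for MED17, and Mediator and stress genes for MED30.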

Other observations

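The depth model was added after the difference in background pileup was seen, and its version with a free exponent, the odds ratios of parental peaks by MED30, the tests of the peak at the MED30 gene, the tests in gene-free stretches other than that of MED17 against parental MYC, and the gene lists matched on parental peaks were chosen after those results were seen. Retention was also matched on the strength of the parental MYC peak in place of the no-doxycycline peak. A peak was kept at 11 of 11 ribosomal protein genes against 7.50 in matched lists (138 of 10000 kept as many, against 4 in the first matching). The counts were 10 of 12 ribosome biogenesis genes against 6.38 (206, and 485 in the first) and 5 of 7 glycolysis genes against 2.68 (589). Translation factor genes kept 9 of 12 against 6.95 (1557) and nucleotide synthesis genes 5 of 9 against 4.35 (4499). MED17 peaks without MED30 lay mostly in the weaker part of their list, 32.4% of 3757 (30.9 to 33.9%) being in the upper 50% by fold, below the bound of 35% set beforehand for weak peaks.

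Most MYC peaks called without doxycycline were not called with it. On chromosome arms, lower depth may account for most of the fall in the number of parental MYC peaks called, from 1936 to 1114. The depth model predicts that number and not which peaks are kept, so it does not decide the loss of individual peaks. Of 10447 parental MYC peaks on arms with a recovered pileup, the doxycycline list held 1114, 1.02 times the 1097 predicted from the no-doxycycline list by lowering depth alone (0.963 to 1.07, over draws of peaks). The model misses the shape of the data, with 53.5% observed and 39.2% predicted in the top of 10 bins of parental peaks; a version with a free exponent gave 0.947 times the predicted number on arms (0.893 to 0.995), and the first version gave 0.858 times (0.811 to 0.914) in gene-free stretches and contigs. No comparison of sites with and without MED30 departs, beyond its interval, towards a loss of MYC concentrated at MED30 sites, and a small one remains open. With MED30 over without, the enrichment ratio was 1.01 (0.943 to 1.10) and observed over predicted number with the free exponent 0.958 (0.827 to 1.08). That number was 0.936 with MED30 (0.879 to 0.998) and 0.977 without (0.862 to 1.10). In strata of parental pileup and gene boundary status, the odds ratio of parental peaks being called, by MED30, was 0.835 without doxycycline (0.721 to 0.967). It was 0.869 with doxycycline (0.724 to 1.04), 1.04 times as high (0.845 to 1.249). The odds ratio of 1.83 at equal no-doxycycline fold does not decide this. Fold in this shallow library is a rough measure of site strength, and the ratio was 1.44 among peaks with a parental MYC peak. Doxycycline and library cannot be told apart in this comparison, since each condition has 1 library and no cells without the hairpin were given doxycycline.

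MED17 peaks in gene-free stretches, mostly around centromeres, may reflect signal common to several antibodies, such as repeats collapsed in the assembly or regions of high copy number. Of 953 MED17 peaks there, 88.1% (85.9 to 90.1%) overlapped a parental MYC peak, although the antibodies and the fixation differed; random placement in the same stretches gave 5.76% on average. Fewer overlapped MED30 (56.2%, 53.0 to 59.4%) or MYC of the shallower shMED30 line (61.0% without and 39.5% with doxycycline), against 2.06%, 6.94% and 3.73% at random, so not all of this signal was called in every library. The random positions were not limited to sequence where reads can map. The random shares may therefore be too low, and the gap to them does not by itself show a common signal. In the other direction, 25.1% (23.7 to 26.6%) of 3396 parental MYC peaks there overlapped a MED17 peak, so most of them were not shared with MED17. For the MYC peaks of the shMED30 line, where these stretches hold 60.5% and 54.2% of the lists, a common signal is not decided: 31.0% (29.6 to 32.4%) of 4333 no-doxycycline peaks overlapped parental MYC, but both libraries are of MYC, and the 953 MED17 peaks are too few to test the rest. A shared artefact is not separated from binding of both proteins, as input libraries were not used here.

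The strongest MYC peak at a gene boundary gained with doxycycline lay at MED30, the gene the hairpin targets, 152 to 347 bp from the lower end of the gene. It was 196 bp wide, the smallest width in its list, which 49 peaks share; 0.249% of the 402 doxycycline peaks with a summit pileup of at least 13 were as narrow, that is this peak alone; their median width was 431.5 bp. A candidate explanation is fragments of 1 short MED30 sequence, such as an amplified product or a vector insert, which would give a summit of 13 fragments over a minimal width. The no-doxycycline library of the same line was deeper (background pileup 0.310 against 0.186 fragments) and had no peak there. An insert carried by the line would be present in both libraries, so a vector insert does not by itself explain this difference. MYC binding gained at MED30 during knockdown stays open: of 19 other gene boundary peaks with at least its fold of 10.3, 0 lacked a parental MYC peak, which allows a share of up to 17.6%. The reads across this interval were not analysed here.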
